A study of Mus musculus with 6 samples.

How the data were processed

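Gene expression was measured in whole optic nerve of mice without leukemia inhibitory factor (LIF), bred on the CD1 stock, and of CD1 wild-type mice, at postnatal days 10, 14 and 35. Per the labels' protocols, each array was hybridised with RNA of a pool of 10 nerves at day 10, 8 nerves at day 14 and 4 nerves at day 35, extracted with TRIzol, and 500 ng of it was amplified and biotin-labelled with the Illumina TotalPrep kit. The groups are genotype by age, with 1 array in each of 6 groups, taken from the labels. Per the file headers, the arrays were MouseRef-8 BeadChips, which carry probes on beads and are read in 1 colour, and the scanner output was exported from BeadStudio 1.5.0.34 with no normalization. The deposited per-array files hold, for 24611 probes including 5 control rows that were left out, the mean bead intensity on a linear scale, per the file headers. They also hold a detection score from 0 to 1 per probe, which the authors exported from the same program and which was read as 1 minus the detection p-value. The authors' deposited table of the whole series holds the same intensities multiplied by 1 factor per array, which makes the mean of both arrays of an age equal. It leaves 15646 of its 24613 probes blank, by a rule not given in the sources used here.

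The per-array files name probes by design identifiers without gene names, while the deposited table carries Illumina identifiers that a reference table pairs with genes. Probes were linked by their values: the 6 intensities of a table probe divided by the array factors had to match 1 file row within 0.05 signal units. Of the 8426 table probes with values on all 6 arrays, 8407 matched 1 row and 19 none. Of the 538 with values on the day 35 arrays alone, 529 matched, and 3 of 3 with values on the other arrays alone. As a check that did not use values, the gene number inside the design identifier was compared with the gene identifier of the linked probe. It was equal for 97.1% of the 2998 probes that carry one and matched on all 6 arrays. It was also equal for 97.3% of 186 matched on the day 35 arrays alone and for 2 of 2 on the others. In a test on simulated data, 2000 of 2000 probes were linked to the right row. With 2 rows left out that several table probes matched, 8935 probes were linked, and 8047 of them had 1 gene symbol (6656 genes), 888 had none. The reference assembly GRCm38.p6 gave chromosomes and replaced 0 symbols, and no coordinates are given because the build behind the array design is not given in the sources used here.

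Intensities were corrected for background with the normexp model of limma 3.58.1 in R 4.3.3, which took the negative control distribution from the detection p-values, with an offset of 16. They were then quantile normalized and taken to log2. A probe was tested if its detection p was below 0.05 on at least 2 of the 6 arrays, which left 13827 probes, of which 10656 were detected on all 6. For lists, correlations and the fixed genes, a gene was represented by its probe with the highest mean log2 signal, which gave 6616 named genes. In rankings, which ran over probes, a gene is named by its ranked probe, and the value of a brighter probe that differs is given beside it. Probes without a name were tested and counted and are not named.

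With 1 array per genotype and age, a difference at a single age has no replicate and no test, and is given as a value. Tests pooled the arrays: lmFit and eBayes (two-sided) with day as a factor and genotype as a term used the 3 ages as replicates of the genotype difference and both genotypes as replicates of an age, with 2 residual degrees of freedom and 3.68 prior degrees of freedom. A second model added a term for the genotype difference at day 10 against a common difference at days 14 and 35, with 1 residual degree of freedom. P-values were adjusted by Benjamini-Hochberg over all 13827 probes and the threshold was an adjusted p of 0.05. The p-values of probes measure how far single pooled arrays scatter around these models, since no group had a second pool. In tests on simulated arrays with 200 of 13827 probes changed, a change of 1 log2 unit was recovered in 32.7% of probes for the genotype difference and in 5.2% for day 35 minus day 10. A change of 2 log2 units was recovered in 93.8% and 83.5%. For the term of day 10 against the other ages 0% was recovered at either size, so that its count of 0 says little. With 4000 probes changed by 1 log2 unit, 83.1% were recovered for day 35 minus day 10, with 123 false among 3450 calls.

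The design, the alternatives, the rule for named genes and 19 gene lists (341 genes) were written before the data were examined. The lists cover myelin and mature oligodendrocytes, newly formed oligodendrocytes, oligodendrocyte precursors, cholesterol synthesis, astrocytes, microglia and macrophages, endothelial cells, mural cells, meningeal cells and fibroblasts, the cell cycle, the LIF receptor and STAT3 pathway, immediate early genes, interferon and antigen presentation, neurons, retina and lens, skeletal muscle, red blood cells, Schwann cells and a sex check. The 16 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes. At that setting camera sets the genes of a list against all other genes, so its p-values reflect the spread between genes and not between pools. The lists were tested again with an estimated correlation, and with fry. The estimated correlation rests on the 1 or 2 residual degrees of freedom of each model. Only the preset correlation was tried on simulated lists, so how often the estimated one finds a true change is not known. At single ages, a list's median was ranked among 10000 random lists of the same size matched on mean expression, with a 95% interval from 2000 bootstrap draws over its genes. Intervals of this kind cover the spread between genes and not between pools. The named genes are the 10 highest and the 10 lowest past the threshold with the same sign in every pair (5 and 5 for day 14 minus day 10 and for day 35 minus day 14). Where fewer passed, the places went to the genes of the same sign in every pair with the lowest unadjusted p. At each age the 5 highest and the 5 lowest differences among probes detected on both arrays were added, with a fixed set of myelin, oligodendrocyte, astrocyte and LIF pathway genes, and up to 4 leading members of each list. Where a probe was not above background on every array of a group, the fold is given as a bound, from the mean of the brighter group over the mean of, per array of the dimmer group, the higher of the lowest signal among detected probes and the probe's own signal. Members of the lists without a linked probe, such as Lifr, were not analysed here.

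Alternatives were no background correction, normexp without detection p-values, no normalization between arrays, scaling to the 75th percentile, cyclic loess, no filter on dim probes, a filter on all 6 arrays, an intensity trend in eBayes, the authors' deposited table, no age block, the mean of a gene's probes, and leaving out arrays or ages. Figures were drawn with matplotlib 3.10.9. The number of arrays, 6, limits the precision of every value.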

Results

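The series asks how leukemia inhibitory factor, a cytokine of the interleukin-6 family that signals through gp130 and STAT3, bears on the timing of oligodendrocyte maturation and myelin formation in the mouse optic nerve. The nerve holds the axons of retinal ganglion cells with their oligodendrocytes, astrocytes, microglia, vessels and sheath. Expression was measured on 6 arrays, 1 for LIF knockout and 1 for CD1 wild type at each of days 10, 14 and 35, the last being adult, each from a pool of nerves labelled male. Between 12222 and 13292 probes were detected per array, with median signals of 51.8 to 61.9 and mean signals of 236 to 310.0. The arrays of days 10 and 14 shared 1 slide and those of day 35 another, so every difference between genotypes lies within a slide, while changes up to day 35 cannot be told apart from the slide. The 18S control probe read 3061 to 3812 on the first slide and 1576 to 1655 on the second.

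The Lif probe was close to background on all 6 arrays, with detection p between 0.005 and 0.029. The normalized log2 signal of Lif was 5.71 in the knockout and 5.47 in the wild type at day 10, 5.13 and 5.48 at day 14, and 5.14 and 5.04 at day 35. Where this probe lies relative to the disrupted part of the gene is not given in the sources used here, so it does not check the genotype labels. Of the sex check genes, Eif2s3y and Kdm5d, both on the Y chromosome, were measured. On the day 35 knockout array neither was above background, with raw signals of 39.5 and 37.5. On the day 35 wild-type array the signals were 72.3 and 141, both detected. Eif2s3y was also at background on the day 10 wild-type array, at 55.4, against 396.4 in the knockout of that age, while Kdm5d was detected on both at 97.2 and 73.8. At day 14 both genes were detected in both genotypes, with Eif2s3y at 523.7 in the knockout and 701.5 in the wild type and Kdm5d at 139 and 168.5. These Y-linked values stand beside each genotype difference at days 10 and 35 given here.

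At day 10 the knockout nerve had lower signals for myelin genes. Markers of other tissues also differed in that pool, with medians of 0.43 for endothelial, 0.50 for mural and -0.45 for skeletal muscle genes. The myelin and mature oligodendrocyte list had a median difference, knockout minus wild type, of -0.89 log2 units (95% interval over genes -1.47 to -0.45), with 22 of its 24 measured members below 0 and a percentile of 0 among 10000 random lists. The differences were -2.79 for Trf, the iron carrier transferrin, -2.56 for Mal, a membrane protein of compact myelin (-1.18 on its brighter probe), -2.28 for Gjb1, the gap junction protein of the connexin family, -2.13 for Apod, a lipid-binding apolipoprotein, and -2.05 for Opalin, a glycoprotein of oligodendrocytes. Mog, the myelin oligodendrocyte glycoprotein, differed by -1.62 and Cnp, an enzyme of noncompact myelin, by -0.93, while Mobp differed by -0.34. Cntn2, the adhesion molecule TAG-1 of the region beside the node of Ranvier, differed by -3.71, from 9.15 in the wild type to 5.44 in the knockout. Mbp is among the brightest probes, with raw signals of 18693 and 18481, and quantile normalization gave it the same value in both genotypes at each age, so its difference of 0 is not informative. Mag, the brightest probe on both day 14 arrays, is likewise set by rank there.

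Genes of cholesterol synthesis, which supplies the main lipid of myelin, went the same way at day 10. All 16 measured members were below 0, with a median of -0.55 (interval -0.68 to -0.31), including -1.30 for Dhcr7 and -1.02 for Cyp51, enzymes of the last steps and of lanosterol demethylation. The cell cycle list went the other way, with a median of 0.43 (interval 0.34 to 0.50) and 22 of 24 members above 0, such as 1.29 for Tk1, thymidine kinase, and 0.82 for Ccna2, cyclin A2. Lists of earlier stages of the oligodendrocyte lineage lay near 0. Their medians were 0.10 for newly formed oligodendrocytes (interval -0.48 to 0.28) and -0.10 for precursors (interval -0.28 to 0.68). In the latter list Pdgfra, the receptor that drives precursor division, was at 0.68 and Matn4, a matrilin of the extracellular matrix, at -1.16. Cspg4, Olig1, Olig2 and Sox10 were at -0.17, -0.28, -0.48 and -0.12. The astrocyte list had a median of 0.09, with members on both sides such as -1.72 for Clu, clusterin, and 1.03 for Glul, glutamine synthetase. Gfap, the intermediate filament of astrocytes, was at -0.84.

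**Figure D1:**
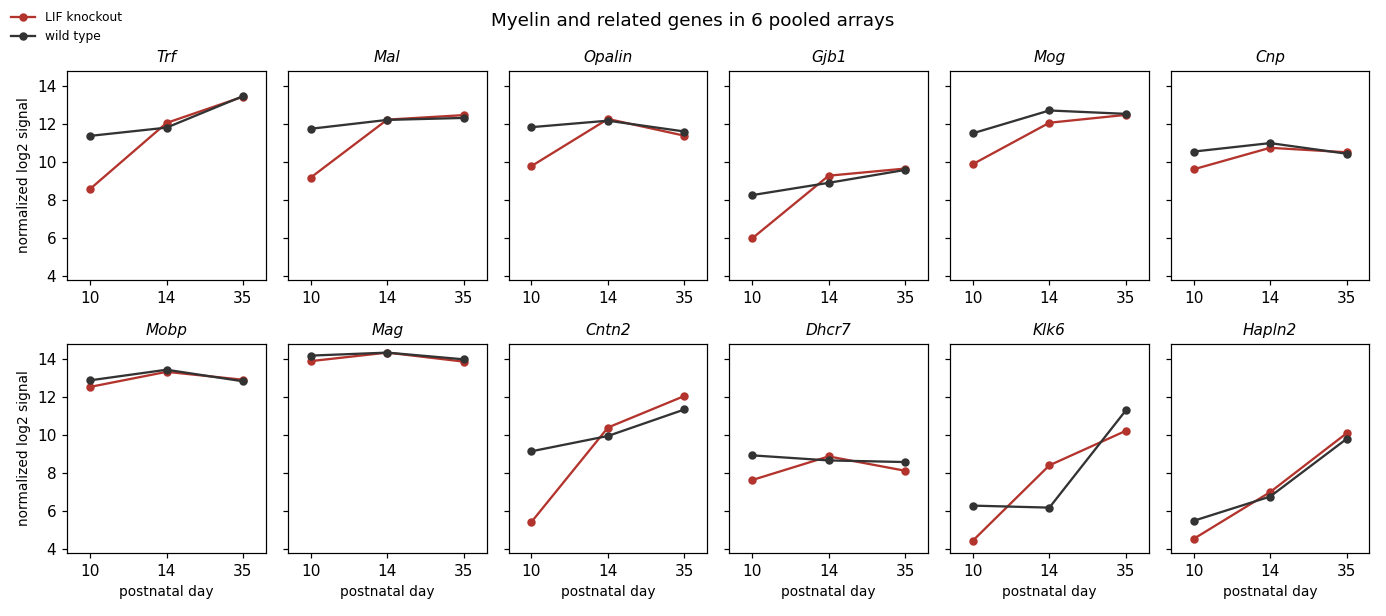
Normalized log2 signal (vertical axis) against postnatal day (horizontal axis, evenly spaced categories) for 12 genes, with LIF knockout in red and wild type in black and 1 pooled array per point, so there are no error bars. At day 10 the knockout lies below the wild type for each gene shown (Mal by the probe with the larger difference), with a difference of -2.79 log2 units for Trf and -0.34 for Mobp, and at days 14 and 35 most pairs lie close together, with Klk6 as the widest exception.

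At days 14 and 35 the myelin difference was small. The median of the myelin list was -0.04 (interval -0.20 to 0.07) at day 14 and -0.02 (interval -0.09 to 0.07) at day 35, and that of cholesterol synthesis -0.04 and -0.09. Trf stood at 0.25 and -0.03, and Mog at -0.64 and -0.05. An exception was Klk6, a secreted serine protease of mature oligodendrocytes, which was 2.22 higher in the knockout at day 14 and had a difference of -1.08 at day 35. Without normalization between arrays the myelin median at day 14 was -0.30, and that of the cell cycle list, 0.20 as normalized, was -0.03. The medians of the newly formed oligodendrocyte, precursor and astrocyte lists at these ages lay between -0.09 and 0.02.

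Whether the genotype difference of day 10 differed from a common difference at days 14 and 35 was tested in limma with a separate term. No probe passed (733 of 13827 at an unadjusted p below 0.05, lowest adjusted p = 0.884). As values, the term was -4.29 ± 0.29 (SE) for Cntn2 (limma adjusted p = 0.884), -2.90 ± 0.29 for Trf, -2.64 for Mal (-0.93 on its brighter probe), -2.50 for Gjb1 and -2.02 for Apod, all lower in the knockout at day 10. The values for Ccl21b, a chemokine, H2-T23, a nonclassical histocompatibility molecule, and Clec10a, a lectin of macrophages, were -2.75 (-2.67 on another probe), -2.46 and -1.88. The values for Gpr182, a receptor of endothelial cells, and Tmod1, an actin-capping protein, were -2.05 and -2.13. On the positive side stood Ucp1 at 5.96, the uncoupling protein of brown fat, Sparc at 3.41, a matrix-binding glycoprotein, Pttg1 at 2.32, the securin of mitosis, Tnni1 at 2.06, a troponin of slow muscle, and Cxcr4 at 1.92, a chemokine receptor. C1qtnf3, Fbln2, Nup88 and Ggcx were at 1.84, 1.94, 1.76 and 1.71. The terms of Ucp1, Tnni1, Ggcx and Ccl21b include arrays on which the probe was at background, and that of Eif2s3y, also positive, is left without a value because it was at background on 1 array of each genotype.

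By list, the term was negative for myelin (median -0.82, camera adjusted p = 1.01e-12), cholesterol synthesis (median -0.45, adjusted p = 0.000494) and skeletal muscle (median -1.33, adjusted p = 0.0288), and positive for the cell cycle (median 0.46, adjusted p = 0.00045) and endothelial genes (median 0.45, adjusted p = 0.0174). None of the 5 passed with an estimated correlation (camera adjusted p = 0.86 for each). That estimate had 1 residual degree of freedom here, and no list passed it in any contrast, so it cannot decide whether they hold. With fry none of the 5 passed either, with adjusted p from 0.186 for myelin to 0.903 for skeletal muscle. The medians at days 10, 14 and 35 were -0.45, -0.84 and 2.92 for skeletal muscle, where day 35 lay apart, and 0.43, -0.42 and 0.27 for endothelial genes, where day 14 did. For the myelin list, 0 members passed over all probes and 6 fell below 0 past the threshold when adjusted over the list alone. The limma test of this term recovered 0% of simulated changes of 2 log2 units. Without normalization between arrays 4 probes passed, those of Cntn2 (-4.10), Ucp1 (6.19), Sparc (3.68) and Eif2s3y.

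Over the 3 ages together, the knockout and the wild type did not differ past the threshold at any probe. In limma 0 of 13827 probes passed, with 520 (3.76%) at an unadjusted p below 0.05 and a lowest adjusted p of 0.526. That lowest value belonged to Snx5, a sorting nexin of endosomes, with a difference of -1.59 ± 0.14 (SE, 3 pairs) and values of -1.61, -1.41 and -1.76 at the 3 ages. Other genes that kept 1 sign were lower in value for Prkd3, protein kinase D3 (-1.65), Eif4e, the cap-binding translation factor (-1.36), Rplp0, a ribosomal protein (-1.05), Mrps17 (-0.89), Ptpn9 (-0.79), Abhd1 (-0.75), Tspan17 (-0.69), Ggt7 (-0.68) and Notch3, a receptor of mural cells (-0.62). Higher in value were Gbp2b, an interferon-induced GTPase (1.58), H2-Aa, a chain of class II histocompatibility molecules (1.54), Ndufb10, a subunit of respiratory complex I (1.33), Ring1, a polycomb protein (1.0), Stk32a (0.91), Pcdhb14 (0.89), Wee1, an inhibitory kinase of mitotic entry (0.83), Cckbr (0.82, at least 1.65-fold), Atxn1 (0.67) and Bex1 (0.61). Each of these had an adjusted p of 0.875 or 0.989. A brighter probe gave 0 for Rplp0, 0.08 for Bex1, -0.18 for Abhd1 and -0.13 for Tspan17. Ring1 and Bex1 were detected on 1 of 3 wild-type arrays and Wee1 on 2, and Eif4e and Rplp0 on 2 of 3 knockout arrays. With day 14 left out 1 probe passed in limma, that of Sspn (adjusted p = 0.0291), at 9.46 and 10.38 in the knockout and 4.32 and 4.53 in the wild type at days 10 and 35, and with day 35 left out 1 passed, that of Cga (adjusted p = 0.00956), at 5.31 and 4.83 in the knockout and 9.09 and 9.17 in the wild type at days 10 and 14, both named after their values were seen.

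At the level of lists, this comparison over ages gave a lower myelin list (median -0.26, camera adjusted p = 3.61e-06), a lower cholesterol synthesis list (median -0.21, adjusted p = 0.000131), and higher retina and lens (median 0.66, adjusted p = 0.00276) and cell cycle lists (median 0.17, adjusted p = 0.0132). None passed with an estimated correlation, which had 2 residual degrees of freedom here (camera adjusted p = 0.99 for all 4). Fry passed none of the 4 either (fry adjusted p = 0.976 for each). No member of the myelin, cholesterol, retina or cell cycle list passed on its own, over all probes or adjusted over the list alone. The other 12 lists did not pass, with adjusted p between 0.26 for skeletal muscle and 1 for astrocytes. Among them, the interferon and antigen presentation list had a median of -0.28, a mean of 0 and a camera direction of down, with 1 member higher when adjusted over the list alone, H2-Aa.

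The LIF receptor and STAT3 pathway list had a median over 21 members of -0.27 at day 10 (interval -0.48 to -0.01), 0.25 at day 14 (interval 0.09 to 0.45) and -0.23 at day 35 (interval -0.35 to 0.06), and -0.07 over the ages (camera adjusted p = 0.956). Over settings the medians ranged from -0.40 to -0.14, from 0.04 to 0.26 and from -0.23 to -0.01. Serpina3n, an acute-phase serine protease inhibitor and STAT3 target, was at -2.27, 2.3 and -1.82, Osmr, the oncostatin M receptor, at -0.96, 1.08 and -1.52, and Socs3, the feedback inhibitor of gp130 signalling, at -0.65, 1.18 and -1.47. Il6st, which encodes gp130, was at 0.42, -0.11 and -0.58. Microglia and macrophage genes had medians of -0.06, 0.66 (interval 0.51 to 0.87) and -0.51 (interval -0.78 to -0.45). At day 14 C1qc and C1qb, chains of complement C1q, stood at 1.02 and 0.94 and Fcrls, a microglial receptor, at 1.95, and at day 35 Fcgr3, an antibody receptor, stood at -1.62. Within this list Fcer1g was at background in the wild type at each age and at least 7.57-fold higher in the knockout at day 10 and at least 16.5-fold at day 35, and at day 14 it was at background in both. The interferon and antigen presentation list had medians of -0.42, 0.18 and -0.39, with -0.03 at day 14 without normalization between arrays and a mean of 0.15 at day 35, where H2-D1 stood at 4.5.

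Markers of vessels and of other tissues differed between the pools at single ages. Endothelial genes had medians of 0.43, -0.42 and 0.27 and mural genes 0.50, -0.21 and 0.18, with Acta2, smooth muscle actin, at 0.85 on day 10, at least 4.89-fold lower on day 14 and at 1.66 on day 35. Meningeal and fibroblast genes lay at 0.22, -0.01 and 0, with Sparc at 2.80 and Col3a1, a collagen, at 1.04 on day 10. Immediate early genes lay at 0.05, -0.09 and 0.28, and neuron genes at 0.09, 0.20 and 0.34. The retina and lens list lay at 0.72, 1.44 (interval 0.90 to 2.75) and -0.28, and at day 14 the rod genes Sag and Gnat1 were at 3.05 and 2.75 and Nrl at least 4.05-fold higher. Skeletal muscle genes lay at -0.45, -0.84 and 2.92 (interval 1.57 to 3.8), and at day 35 the difference was 6.09 for Acta1, skeletal actin, 5.40 for Atp2a1, the calcium pump of fast muscle, 3.94 for Tnnc2 and 3.8 for Tnni2. The red blood cell list, with 4 measured members and no test, lay at 0.48, -0.41 and -0.79, and the Schwann cell list, also with 4, at -0.07, 0.09 and -0.24. The sex check list, with 2 members, lay at 1.40, -0.12 and -1.91.

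**Figure D2:**
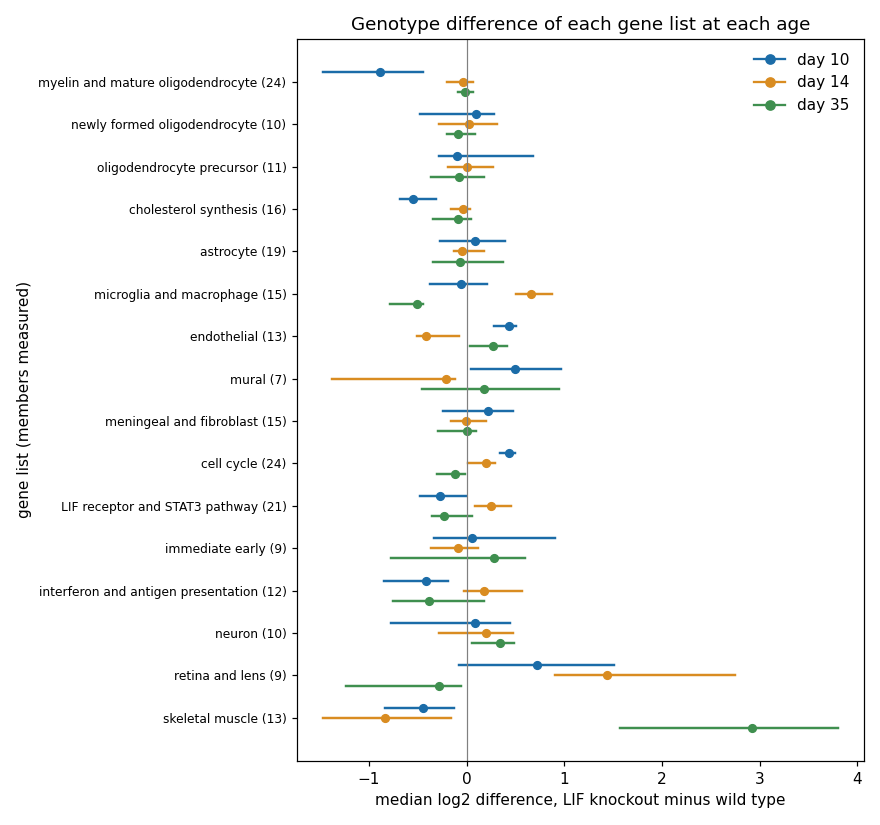
Median log2 difference, knockout minus wild type (horizontal axis), of 16 gene lists with the number of measured members in brackets (vertical axis) at days 10, 14 and 35, with 95% bootstrap intervals over the genes of a list, not over pools. The myelin list lies at -0.89 at day 10 and near 0 at the other ages, and the skeletal muscle list at 2.92 at day 35.

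**Figure D3:**
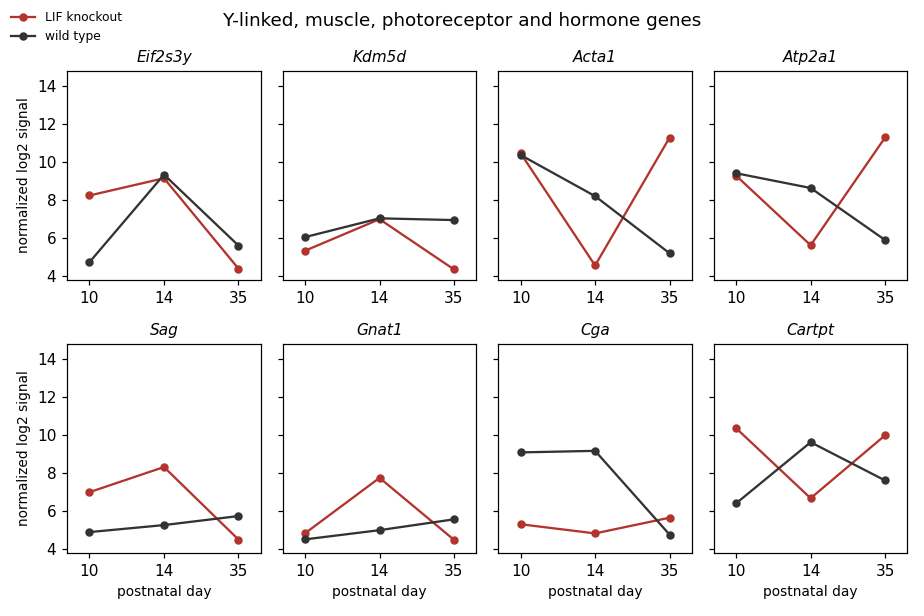
Normalized log2 signal (vertical axis) against postnatal day (horizontal axis, evenly spaced categories) for 2 Y-linked genes, 2 muscle genes, 2 rod photoreceptor genes and 2 hormone or neuropeptide genes, with 1 pooled array per point and no error bars. Both Y-linked probes are at background in the day 35 knockout array, where Acta1 and Atp2a1 stand at 11.29.

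Among probes detected on both arrays of an age, the 5 highest and 5 lowest differences included these genes. At day 10 Ucp1 was at 4.89, Cartpt, a neuropeptide precursor, at 3.95, Pdrg1 at 2.86 and Hbb-b2, a beta globin, at 2.85, while Cga, the common alpha chain of pituitary hormones, was at -3.78 (at day 14 it was at background in the knockout, against 9.17 in the wild type) and Ccl21b at -2.98. At day 14 Cartpt stood at -2.94, Chga, chromogranin A of secretory granules, at -2.49 (-2.07 at day 10, and at background in both genotypes at day 35), Pdrg1 at -2.01 and Actg2, enteric smooth muscle actin, at -1.71. At day 35 Fbxw5, Insm1, Hbb-bt, Cela1 and S100a4 stood at -3.20, -2.93, -2.80, -2.28 and -2.12. At days 10 and 14 Fbxw5 stood at -2.46 and -0.32 and S100a4 at -2.30 and 1.09. The spread of the difference over all probes, as an SD, was 0.447 at day 10, 0.33 at day 14 and 0.417 at day 35. Probes with a difference beyond 1 log2 unit numbered 227 higher and 234 lower at day 10, 67 and 90 at day 14, and 209 and 143 at day 35.

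Across 6616 named genes, which are not independent replicates, the genotype differences of different ages showed little shared pattern. Pearson's r was -0.076 between days 10 and 14 (Spearman's rho -0.078), 0.157 between days 10 and 35 (0.145) and -0.256 between days 14 and 35 (-0.177). The difference at day 10 had r = -0.111 (rho -0.057) with the change from day 14 to day 35, measured on other arrays. The difference at day 14 had r = -0.10 (rho -0.14) with the change from day 10 to day 35, and that at day 35 r = -0.014 with the change from day 10 to day 14. Changes with age had higher correlations between genotypes. Those up to day 35 cross from 1 slide to the other in both genotypes, so the slide can raise them. For day 35 minus day 10 the wild-type and knockout changes had r = 0.716 and for day 35 minus day 14 r = 0.602. For day 14 minus day 10, within 1 slide, the changes had r = 0.307. These are among 11 relations computed, with no p-value.

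Between day 10 and day 14 the signals of myelin genes were higher and those of cell division genes lower, without a probe past the threshold. Limma called 0 of 13827 probes, with 1719 (12.4%) at an unadjusted p below 0.05 and a lowest adjusted p of 0.237. The cell cycle list was lower (median -0.98, camera adjusted p = 3.51e-14), and 15 of its 24 members fell when adjusted over the list alone, including Bub1b, a mitotic checkpoint kinase (-1.36 ± 0.18 SE; list adjusted p = 0.567 with an estimated correlation). The myelin list was higher (median 0.92, adjusted p = 4.17e-12), and 7 of 24 rose when adjusted over the list alone (adjusted p = 0.567 with an estimated correlation). Cholesterol synthesis was higher (median 0.37, adjusted p = 8.14e-05), and skeletal muscle (median -1.87, adjusted p = 0.000498) and meningeal and fibroblast genes (median -0.39, adjusted p = 0.00344) lower, with Col1a2 and Col3a1 at -1.47 and -1.35. These 3 did not pass with an estimated correlation either (camera adjusted p = 0.567). With fry no list passed here, with a fry adjusted p of 0.285 for the cell cycle and for myelin. Mog went from 9.89 to 12.07 in the knockout and from 11.51 to 12.71 in the wild type. Genes with the lowest p were Etnppl, an astrocyte phospholyase (at least 6.05-fold), Slpi (1.56), Acer2, a ceramidase (1.40), H2-Q6 (at least 1.84-fold) and Erdr1 (1.22, and 0.80 on its brighter probe) on the higher side, and Myl2 (-1.86, detected on 1 of 2 day 14 arrays), Fap, a protease of fibroblasts (-1.76), Rplp0 (-1.69, and -0.67 on its brighter probe), Slc4a1, the anion exchanger of red cells (-1.39), and Dct, a melanin enzyme (-1.38) on the lower. With either day 35 array left out, which leaves the 4 arrays of the first slide to set the spread, 7 probes passed, 2 higher (H2-D1, at least 7.1-fold, and Psmc1 at 2.56) and 5 lower (Myh2, at least 5.06-fold, and 4 without a name), a choice made after the data were seen.

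From day 14 to day 35, 2060 probes passed in limma, 1071 higher (645 named genes) and 989 lower (630 named genes). Gna12, a G protein alpha subunit detected on 1 of 2 day 14 arrays, rose by 3.16 ± 0.42 (SE, adjusted p = 0.0199), Hapln2, a link protein of the nodal matrix, by 3.06, and Fgf1, acidic fibroblast growth factor, by 2.95. Gh, growth hormone, was at background at day 14 and at least 7.16-fold higher at day 35, and Spock1, a matrix proteoglycan, at least 6.87-fold higher. Cemip2, a hyaluronan-degrading membrane protein, changed by -3.34 (-2.63 on its brighter probe), Npb, neuropeptide B, by -3.01, Onecut2, a transcription factor, by -2.99, Rnf122 by -2.92 and St8sia3, a sialyltransferase, by -2.80 (adjusted p from 0.0142 to 0.0173). Rnf122 and St8sia3 were detected on 1 of 2 day 35 arrays. Gfap rose by 2.01 (adjusted p = 0.019).

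Newly formed oligodendrocyte genes were lower at day 35 than at day 14. Of 10 measured members, 5 fell and none rose, with 8 fallen when adjusted over the list alone (median -1.26, camera adjusted p = 0.00247). The camera adjusted p was 0.878 with an estimated correlation, and the fry adjusted p was 0.00689 (down). The fallen members included Nfasc, neurofascin (-2.25), Cnksr3 (-2.01), Rras2 (-1.63) and Tcf7l2, a transcription factor of premyelinating cells (-1.48). Of 24 cell cycle genes 6 fell and 1 rose, and 11 fell and 2 rose when adjusted over the list alone (median -0.57, adjusted p = 0.00506; adjusted p = 0.915 with an estimated correlation), with Cdc20, the activator of the anaphase complex, at -1.59. Of 15 microglia and macrophage genes 3 rose, the same number adjusted over the list alone (median 0.53, adjusted p = 0.0124; adjusted p = 0.915 with an estimated correlation), including Lyz2, lysozyme (2.53), and Ctss, cathepsin S (1.69). The myelin list did not pass (median 0.36, adjusted p = 0.165): Hapln2 and Car2, carbonic anhydrase 2 (2.73), rose and Sirt2, a deacetylase of oligodendrocytes, fell (-2.24). Astrocyte genes had a median of 0.36 (camera adjusted p = 0.111, fry adjusted p = 0.00689, up), and 3 of 19 rose, Gfap, Ntsr2 (1.52) and Fgfr3 (0.71). The cell cycle and microglia lists did not pass with fry (fry adjusted p = 0.437 and 0.572). Skeletal muscle genes had a median of 1.27 (adjusted p = 0.111), and -0.55 in the wild-type pair alone. The count of 2060 rested on the spread of all 6 arrays. It was 0 without the day 10 knockout, the day 10 wild-type or the day 14 wild-type array, 15 without the day 14 knockout array, 92 without the day 35 knockout array and 962 without the day 35 wild-type array.

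Over the whole interval from day 10 to day 35, most genes of the myelin list rose and most of the cell cycle list fell. In limma 2880 probes passed, 1471 higher (887 named genes) and 1409 lower (902 named genes). Klk6 rose by 5.39 ± 0.92 (SE, adjusted p = 0.02), Hapln2 by 4.93 ± 0.33 (adjusted p = 0.00873), Fgf1 by 4.48, Cntn2 by 4.41, Sgk1, a glucocorticoid-induced kinase, by 4.10 (1.68 on its brighter probe, adjusted p = 0.0825), Anln, the septin-binding protein anillin, by 3.98, Car2 by 3.86, Gpnmb, a glycoprotein of phagocytes, by 3.69, and Trf by 3.47. Etnppl was at least 10.8-fold higher. Genes for replication-dependent histone H2A changed by -3.54 (H2ac22), -3.25 (H2ac10), -3.21 (H2ac12), -3.15 (H2ac13) and -2.94 (H2ac23), and since these genes are near-identical their probes may share signal. Prnd, the prion-like protein doppel, was at least 8.29-fold lower, and Car3, carbonic anhydrase 3, Rnf122, Col26a1, a collagen, and Cemip2 changed by -3.38, -3.11, -3.07 and -2.93. Klk6 and Hapln2 were detected on 1 of 2 day 10 arrays, and Rnf122 on 1 of 2 day 35 arrays. The rises of Cntn2 and Trf were 6.62 and 4.85 in the knockout and 2.20 and 2.09 in the wild type.

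By group, 18 of 24 cell cycle genes fell and none rose, 20 adjusted over the list alone (median -1.55, camera adjusted p = 6.39e-08; adjusted p = 0.762 with an estimated correlation). Cdc20 changed by -2.59, Cenpa, the centromeric histone, by -2.52 and Nusap1, a spindle protein, by -2.39, and Cdk1, the mitotic kinase, was at least 4.84-fold lower. Of 24 myelin genes 13 rose and 1 fell, Sirt2, with 15 risen adjusted over the list alone (median 1.42, adjusted p = 9.29e-06; adjusted p = 0.762 with an estimated correlation). Among the fixed genes Mog rose by 1.80 (adjusted p = 0.0274), while Cnp (0.39) and Mobp (0.16) did not pass. The probes of Mag and Mbp are so bright that their normalized values are set by rank, and their changes are not read. Of 10 newly formed oligodendrocyte genes 7 fell, and 9 fell and 1 rose adjusted over the list alone, among them Cnksr3 (-2.02) and Rras2 (-1.59). The median of this list was -1.37 (camera adjusted p = 0.00187, and 0.762 with an estimated correlation, fry adjusted p = 0.00898, down). Of 11 precursor genes 4 fell, the same number over the list alone: Matn4 (-2.0), Dll3, a Notch ligand (-1.72), Tnr, tenascin R (at least 2.68-fold lower), and Sox11 (-1.53). The median of this list was -0.47 (camera adjusted p = 0.0268, and 0.762 with an estimated correlation, fry adjusted p = 0.0203, down). Of 15 microglia and macrophage genes 3 rose (median 0.48, adjusted p = 0.014; adjusted p = 0.762 with an estimated correlation), including Lyz2 (2.17). Astrocyte and cholesterol lists did not pass with camera (adjusted p = 0.237 and 0.594), while astrocytes did with fry (up, adjusted p = 0.0316), and Gfap rose by 1.92 (adjusted p = 0.0127) and Insig1, a regulator of sterol synthesis, by 1.95 (adjusted p = 0.0118). The myelin, cell cycle and microglia lists did not pass with fry (fry adjusted p = 0.166, 0.084 and 0.457). Jak2 (1.26) and Socs2 (0.82) of the LIF pathway list rose. The count of 2880 was 0 without either day 10 array, 515 without the day 35 knockout and 1663 without the day 35 wild-type array. Without normalization between arrays 28.4% of calls were higher against 51.1%, and 19.2% were in the authors' deposited table. The median change of all probes was -0.24 and -0.275 under these settings.

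**Figure D4:**
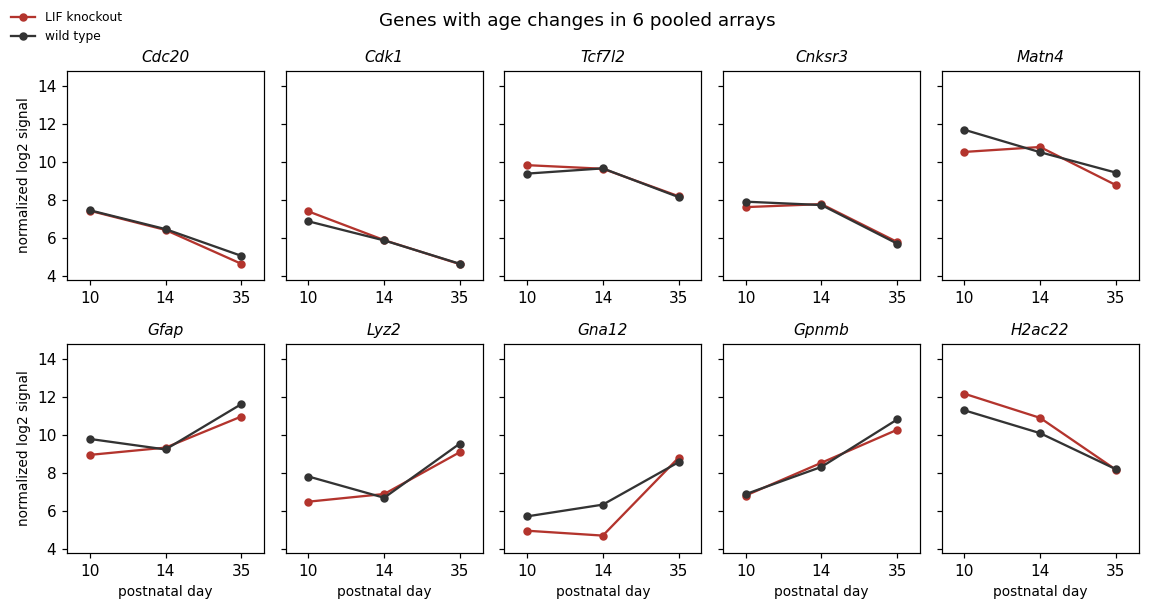
Normalized log2 signal (vertical axis) against postnatal day (horizontal axis, evenly spaced categories) for 10 genes with age changes, with LIF knockout in red and wild type in black and 1 pooled array per point, so there are no error bars. Cdc20 and H2ac22 change by -2.59 and -3.54 between days 10 and 35, and Gfap and Gpnmb by 1.92 and 3.69.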

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

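The tests of the myelin, muscle and Y-linked patterns in this part were chosen only after the result was seen, while the correlation with later development and the splits of the arrays were planned. The term that sets the genotype difference at day 10 against a common difference at days 14 and 35 passed for 5 gene lists, with camera adjusted p of 1.01e-12 for myelin, 0.000494 for cholesterol synthesis, 0.00045 for the cell cycle, 0.0174 for endothelial genes and 0.0288 for skeletal muscle. For each of them the camera adjusted p was 0.86 with an estimated correlation, and none passed with fry (fry adjusted p from 0.186 to 0.903). Single arrays stand behind every age. For 2 of the lists it was not day 10 that lay apart, with medians at days 10, 14 and 35 of 0.43, -0.42 and 0.27 for endothelial genes and -0.45, -0.84 and 2.92 for skeletal muscle.

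The myelin list had a median of -0.89 in the knockout at day 10. Less glia and more of other tissue in the knockout pool, as the whole cause, is argued against by the astrocyte and precursor lists. Their joint median over 30 genes was -0.05 (interval -0.18 to 0.33), while the upper bound for myelin was -0.45. This covers only a loss that these glial lists share. Markers of other tissue went both ways in that pool. Medians were 0.43 for endothelial, 0.50 for mural, 0.72 for retina and lens and -0.45 for skeletal muscle genes. Ucp1 (4.89), Hbb-b2 (2.85) and Sparc (2.80) were higher, and Cga (-3.78) and Chga (-2.07) lower. Whether other differences in tissue content lowered the myelin list was not tested. Background correction and normalization are argued against by the highest myelin median over the other settings, -0.70. A delay in the whole course of development in the knockout stays open. The correlation of the day 10 difference with the change from day 14 to day 35 was -0.111. That met the rule written beforehand, which asked for a negative value beyond 0.1 in size and a lower myelin list. The test as run also asked that every alternative lie beyond 0.1. Over the alternatives the correlation ranged from -0.129 to -0.094, so the test was left undecided. The absence of LIF, a pool of slightly younger animals, an unequal sex of the pools and the sampling of animals may each account for the myelin difference. They cannot be told apart with 1 pool per group. On sex, Eif2s3y was at background in the wild type of day 10, but Kdm5d was detected there, at 97.2 against 73.8 in the knockout.

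The skeletal muscle list was 2.92 higher in median in the knockout at day 35. Muscle attached to the nerves of that pool may be the source: in another list of 36 muscle genes, written after this was seen, 13 of 18 tested genes were more than 1 log2 unit higher (72.2%), short of the 75% set for the test, with 5.23 for Myh4 and 3.34 for Ckmt2. This leaves muscle tissue undecided by that test. A genotype difference that holds at every age is argued against by the median of -0.84 at day 14.

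On the day 35 knockout array, from nerves labelled male, 0 of 2 Y-linked probes were detected. On the wild-type array of that slide 2 of 2 were detected. Dim signal on that slide is argued against for Kdm5d, at 141 there and 168.5 on the day 14 wild-type array. Eif2s3y was dim there, at 72.3 against 701.5, and says little on this. Nerves of female mice in that pool are a possible explanation that the count of 0 of 2 fits, but Eif2s3y was also at background on the day 10 wild-type array, where Kdm5d was detected, so 1 probe alone is a weak guide. If the pool was female, sex and genotype are confounded at day 35, and no biological explanation was tested.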

How the results depend on the processing

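Alternatives chosen after the data were seen are the 4 arrays of the first slide alone, all probes in place of named genes, list tests under other settings, and muscle without the day 35 knockout array. Of the values under alternatives, 48 of 68 counts of probes, 42 of 55 counts of lists, 80 of 81 correlations, 363 of 378 list medians and 805 of 870 list tests were labelled the same, with 51 list tests weaker and 14 stronger. For named genes, 1156 of 1167 tested values and 557 of 563 values at single ages were. Counts were labelled the same if close to the main count, and correlations, medians and single-age values if within the spread. A test was labelled the same if it stayed on the same side of the threshold, and where neither passed, direction was not compared. Most list tests did not pass in the main setting, so these shares overstate how well passing results held. From day 14 to day 35 the count of 2060 was 1064 without normalization between arrays, 1077 without a filter on dim probes and 1238 in the authors' deposited table, and from day 10 to day 35 the count of 2880 was 1909 without the filter. Leaving out arrays gave 0 to 962 and 0 to 2455 calls for these changes, 0 to 7 from day 10 to day 14 (7 with only the 4 arrays of 1 slide) and 0 to 1 between genotypes, where an age was left out. The number of residual degrees of freedom falls from 2 to 1 there, and other causes were not tested. The day 10 term had 4 calls without normalization between arrays. Of the list medians 14 moved and 1 reversed, among them -0.30 for myelin at day 14 without normalization and -0.10 at day 35 with scaling to the 75th percentile, and the cell cycle at day 14 reversed to -0.03 without normalization. Without it, day 14 medians were also -0.29 for cholesterol synthesis, -0.28 for astrocytes, -0.19 for precursors, 0.44 for microglia, -0.54 for endothelial genes, 0.04 for the LIF pathway and -0.03 for interferon, and day 10 medians 0.28 for newly formed oligodendrocytes, 0.59 for endothelial genes and 0.61 for the cell cycle. With the other normexp setting the cell cycle median at day 10 was 0.30 and that of retina and lens at day 14 was 0.73. Over settings the median of retina and lens at day 10 ranged from 0.38 to 0.80 and that of skeletal muscle at day 14 from -1.38 to -0.48. The median of cholesterol synthesis at day 10 ranged from -0.58 to -0.36 and that of endothelial genes at day 14 from -0.54 to -0.21. Medians near 0 that changed sign over settings were newly formed oligodendrocytes at day 14 (-0.24 to 0.02), precursors (-0.13 to 0.08), microglia (-0.20 to 0.15) and neurons (-0.31 to 0.16) at day 10. Precursors at day 14 and meningeal genes at day 35, both at 0, ranged from -0.19 to 0.03 and from -0.09 to 0. The correlation of the day 14 difference with the change from day 10 to day 35 was -0.167 over all probes. With an estimated correlation 0 lists passed in each of the 5 contrasts. With fry 0 passed for genotype, for day 10 to 14 and for the day 10 term. Fry passed 3 for day 10 to 35 and 2 for day 14 to 35, with astrocytes and newly formed oligodendrocytes among the lists of both. With probes detected on all 6 arrays 2 lists passed for genotype and 1 for day 14 to 35, where 7 passed without normalization and 5 in the authors' table. The cause was not tested. Without the day 35 knockout array the muscle median from day 14 to day 35 was -0.55 in place of 1.27. The genotypes were paired by age in the model, and leaving out this age block changed no count of calls between them (0 in limma, with 520 at an unadjusted p below 0.05 in the model with the block). Signal near background limits probes such as that of Lif.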

Other observations

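The tests of chromosomes in this part were chosen only after the result was seen, except the count of called genes near Lif, and the genes in the next paragraph were picked after their values were seen.

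Some probes were bright on part of the arrays and near background on the others. Cga, the common alpha chain of pituitary hormones, had a normalized log2 signal of 9.09 and 9.17 in the wild type at days 10 and 14, against 5.31 and 4.83 in the knockout, and at day 35 it had 4.8 in the wild type and 5.66 in the knockout. Prl, prolactin, was at 9.21 in the knockout and 5.90 in the wild type at day 35. Sspn was at 9.46, 9.88 and 10.38 in the knockout and at 4.32, 10.16 and 4.53 in the wild type. Psmc1 was at 5.59, 8.04 and 7.87 in the knockout and at 4.89, 7.56 and 4.71 in the wild type. Ucp1 was at 11.08 in the knockout at day 10 and 6.19 in the wild type.

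Between genotypes over the 3 ages, 0 probes passed in limma (520 at an unadjusted p below 0.05), so all 10 of the 10 splits of the 6 arrays had as many. The highest other split had 5, with 1051 at an unadjusted limma p below 0.05. It set the knockout arrays of days 10 and 35 with the wild-type array of day 14, so only the day 14 genotypes were exchanged. Some of the splits put both arrays of an age in the same group, and 10 splits are too few for a share under 0.05.

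A knockout bred from other stock can keep donor genes around the target, and stocks can differ elsewhere. The number of called genes was 0, where 20 were needed to test their place near Lif. Of 34 named genes with 1 sign at all ages and an unadjusted limma p below 0.01, 1 lay within 20 Mb of Lif (2.94%, against 0.937% of 6616 genes, Fisher's exact p = 0.275, one-sided), which leaves this open. The genes already named drew the eye to chromosome 17, and a test over 20 chromosomes on those same 34 genes gave 8 on it (Fisher's exact p = 0.000241, adjusted p = 0.00482), among them Prkd3, Ndufb10, H2-Aa, Ring1 and Notch3. That test ran on the genes that gave the idea, so a test on other genes was chosen next. Among 213 genes with p from 0.01 to 0.05, 8 lay on chromosome 17 (3.76%, against 5.11% of all), Fisher's exact p = 0.86, one-sided. By the rule first written for this test, a share not above that of all genes counts against such a segment. That rule was not kept, because the list leaves out the strongest genes and so excludes nothing. The low share gives the idea no support, and a segment that differs between the stocks stays open.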
